A study of Ovis aries with 40 samples.

How the data were processed

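RNA sequencing was carried out on the abomasum (the glandular stomach of ruminants) and the small intestine of lambs, with total RNA extracted with an RNeasy kit, per the labels' protocols. The deposited table holds 1 column of raw counts per library, as the authors made it, with genes named by symbol or by locus identifier, per the file headers. The aligner, the counting tool, the genome build, the annotation and the strand setting are not given in the sources used here, so genes that share reads with a near-identical copy or with an overlapping gene have uncertain counts. DESeq2 is the tool named in the submitters' processing notes, without a version. The table has 21261 lines. Of these, 5 hold annotation text and no counts and were left out, which left 21256 genes, of which 1906 had 0 counts in all libraries and 5116 carried a locus identifier. A RefSeq gene table of the assembly ARS-UI_Ramb_v3.0 was used for names alone, and 20169 of the gene names matched a symbol in it. No coordinates were used. Columns were assigned to samples by the library name in the sample descriptions, and groups were taken from the sample titles. The 40 libraries form 6 groups, and no column was left unassigned.

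Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each tissue, the 3 groups were fitted together after filterByExpr by group and TMM scaling, and pairs of groups were compared with the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference between the tissues in a treatment effect was tested in a fit of all 6 groups, as the log2 fold change in small intestine minus that in abomasum. Log2 fold changes are given with standard errors, and CPM values, scaled by TMM unless stated otherwise, as mean ± SD. Standard errors were derived from the fold change and its F statistic. The 33 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Of the 768 list entries, 639 matched a gene name in the table. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Members were counted as passing over all genes tested and also adjusted over the list alone.

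The rule for named genes took, among genes past the threshold with a symbol and a mean log2 CPM of at least 1, the 10 with the largest log2 fold change in each direction, the 5 with the lowest p where none passed, up to 4 members of each list with the smallest p, and IL4, IL5 and IL13 where tested. For the tissue difference it took the genes named in either tissue and the 5 with the largest difference in each direction. The text names a part of what this rule gives. A gene outside it is said to be so where it appears. Among the genes of this rule that differed between the tissues, 1 is not reported here.

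The libraries labelled control 4 carried the marker genes of the other tissue. The comparisons and gene list tests were therefore run as labelled and again with both of these libraries left out, an alternative chosen after seeing the data. The tests of mean scores, the fit with the share of the top genes and the splits of whole lambs were run with them left out alone. Groups were not reassigned. Alternatives fixed beforehand were DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, RLE scaling, no filter on low counts, a fit of only the groups compared, the replicate number as a factor, an added fold threshold of 1 on the log2 scale, and leaving out each library in turn. For gene lists, camera with an estimated correlation and fry were used. Comparisons that share control libraries were set beside 100 simulations of unchanged groups and beside split controls. Each count was also set beside 100 splits of the same libraries, the real one included, and the tissue difference of infection without the libraries labelled control 4 beside 40 splits of whole lambs.

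The procedures were tested on simulated data in which 200 genes of the real means, dispersions and library sizes were changed. With the libraries labelled control 4 left out, infected against control in abomasum recovered 35.8% of genes changed 1.5-fold, 68.8% of those changed 2-fold and 90.6% of those changed 4-fold, over 15568 genes. In small intestine the shares were 51.5%, 69.2% and 91.9% over 15891 genes. With all libraries they were 25.8%, 57.6% and 87.3% in abomasum over 15516 genes, and 30.3%, 53.1% and 92.3% in small intestine over 15808 genes. In these simulations all libraries of a tissue were drawn from the same gene means before the changes were added. The shares with all libraries therefore do not describe data that hold libraries with the other tissue's markers. The test of the tissue difference recovered 84% of genes changed 4-fold over 16410 genes. Total counts ranged from 27538694 to 44968690 per library. No pair of libraries within a group agreed within sampling noise, the lowest chi-square per degree of freedom being 30.03. Slaughter day, pen and sex are not labelled per library and were not modelled.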

Results

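RNA was sequenced from the abomasum and the small intestine of 20 lambs in 3 groups. Of these, 6 were uninfected and fed ryegrass (control), 7 were infected and fed ryegrass (infected), and 7 were infected and fed red clover (infected red clover, with single libraries named clover and their number). Lambs of both sexes were kept indoors in several pens per group and had the diets for 7 days before infection. Infected lambs received 10000 larvae of Teladorsagia circumcincta, a parasite of the abomasum, 8000 of Trichostrongylus colubriformis, a parasite of the small intestine, and 100 of Haemonchus contortus, a blood-feeding abomasal worm. They were slaughtered on day 31 or 32 after infection. There was no uninfected group on red clover, so infected red clover against control mixes diet with infection, and the effect of diet was measured among infected lambs alone. The 40 libraries held 34740437 ± 4755601 counts (mean ± SD), from 27538694 to 44968690.

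Markers of gastric glands and of absorptive cells separated the tissues in all libraries except those labelled control 4. ATP4A, the catalytic subunit of the gastric proton pump, stood at 1578 to 8909 CPM of total counts in the other 19 abomasum libraries and at 0.158 CPM in the library labelled abomasum control 4. FABP2, the fatty acid binding protein of enterocytes, was at 8999 CPM in that library and at 2.07 CPM or less in the others. In the library labelled small intestine control 4, ATP4A was at 5715 CPM against at most 2.605 in the other small intestine libraries, and FABP2 was at 1.23 CPM against 2612 to 9000. The median correlation of log2 CPM of the library labelled abomasum control 4 was 0.597 with abomasum and 0.973 with small intestine, and that of the library labelled small intestine control 4 was 0.941 with abomasum and lower with small intestine. Counts of genes are therefore given as labelled and with both libraries left out, which leaves 5 control libraries per tissue. From the gene lists onward, values of genes and lists are those without both libraries unless they are said to be as labelled.

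**Figure D1:**
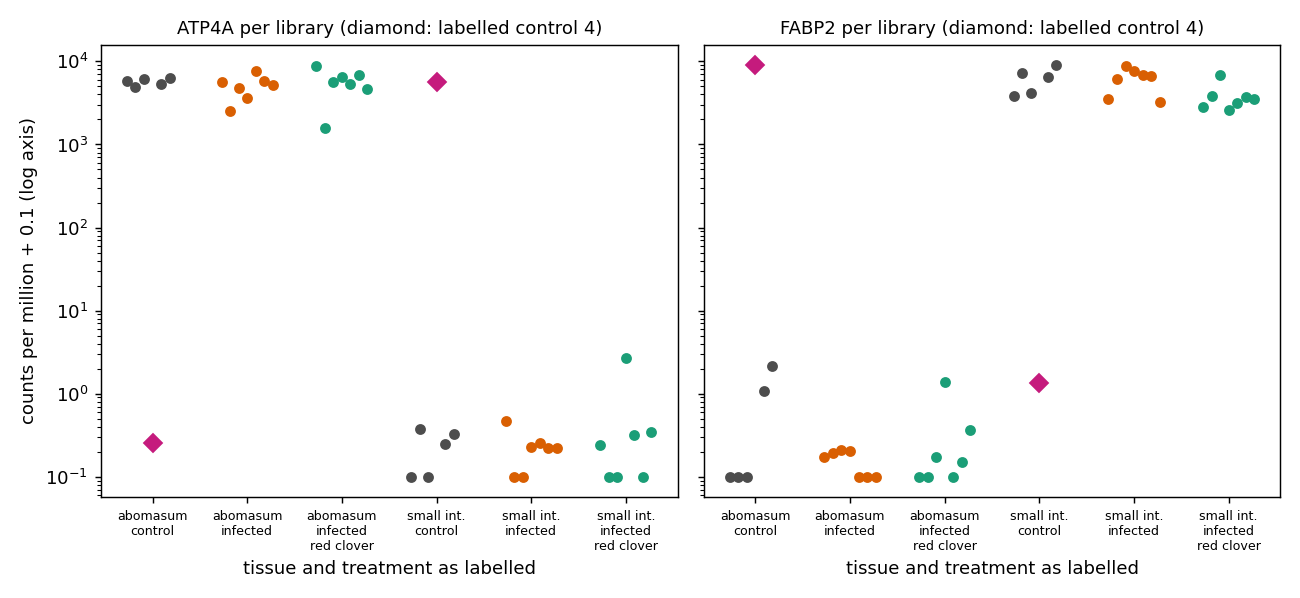
CPM + 0.1 of ATP4A and FABP2 in each of the 40 libraries, on log axes, with diamonds for the libraries labelled control 4. The library labelled abomasum control 4 had 0.158 CPM of ATP4A and 8999 CPM of FABP2, and the library labelled small intestine control 4 had 5715 and 1.23 CPM.

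Infection on ryegrass was first examined in the abomasum. As labelled, 12 genes were higher and 1 was lower in infected than in control lambs among 15654 tested, and most of the named ones belong to tuft cells, the chemosensory epithelial cells that respond to parasites. RGS13 rose by 2.43 ± 0.29 on the log2 scale (adjusted p = 8.73e-04), SH2D6 by 2.68 ± 0.33, IL17RB, a receptor subunit for interleukin 25, by 2.77 ± 0.38, and TRPM5, the cation channel of taste signalling, by 3.03 ± 0.38. POU2F3, the transcription factor that specifies tuft cells, rose by 2.71 ± 0.47 (adjusted p = 0.0281), CHAT, which makes acetylcholine, by 2.49 ± 0.39, and ALOX5, the 5-lipoxygenase of leukotriene synthesis, by 1.75 ± 0.31. HOPX was lower, with a log2 fold change of -1.1 ± 0.19. Without the libraries labelled control 4, 118 genes were higher and 7 lower among 15716, and all 13 calls were among them. DESeq2 also called all 125 of these and limma voom 8. RGS13 then had 1.06 ± 0.439 CPM in controls (SD, n = 5) and 5.7 ± 1.76 CPM in infected lambs (SD, n = 7), and all 7 infected libraries lay above every control.

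Among the gene lists, with those libraries left out, 10 of 23 tuft cell genes rose over all genes tested and 13 adjusted over the list alone, with a median log2 fold change of 1.22 (camera adjusted p = 2.97e-23, and adjusted p = 0.00393 with an estimated correlation). Of 15 mast cell genes 5 rose, and 11 adjusted over the list alone (adjusted p = 5.99e-15, and adjusted p = 0.00338 with an estimated correlation). They included CPA3, a mast cell carboxypeptidase, at 3.47 ± 0.68, MS4A2, the beta chain of the IgE receptor, at 1.96 ± 0.37, and LTC4S, the leukotriene C4 synthase, at 1.44 ± 0.3. The tuft and mast cell lists share 3 genes. Without these, 8 of 20 tuft cell genes and 3 of 12 mast cell genes rose. As labelled, 8 of 23 tuft cell genes and 1 of 15 mast cell genes rose. That mast cell gene was RGS13, which is also on the tuft cell list. Both lists passed with an estimated correlation too (adjusted p = 1.04e-04 and adjusted p = 3.04e-04), with the shared genes kept in. Of 5 genes on the eosinophil and basophil list 1 rose both ways (with an estimated correlation, adjusted p = 0.0146 as labelled and adjusted p = 0.0526 without those libraries). That gene was LGALS15, a galectin gene, and no other gene of the list passed as higher. These calls alone do not show a rise of eosinophils or basophils.

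No gene of the T cell, interferon, B cell or regulatory T cell lists passed over all genes tested as labelled. Several did once the libraries labelled control 4 were left out. In that set, with the share of counts in the 10 top genes as a covariate, the 125 calls of this comparison became 30. Of these 9 were tuft cell genes, so most calls on other genes were lost. Of 26 T cell and cytotoxic genes 9 rose, and 23 adjusted over the list alone, with a median of 1.59 (camera adjusted p = 9.13e-30, but adjusted p = 0.054 with an estimated correlation). CD8A rose by 2.04 ± 0.39 and CD3D by 1.81 ± 0.36, whereas with all libraries CD3D was at -0.03 and did not pass. Of 33 interferon response genes 5 rose and 30 adjusted over the list alone (camera adjusted p = 9.13e-30, but adjusted p = 0.0705 with an estimated correlation). PSMB8, a subunit of the immunoproteasome, rose from 30 ± 6.77 CPM (SD, n = 5) to 129 ± 55.4 CPM (SD, n = 7), TAP1, a peptide transporter for antigen presentation, rose by 1.57 ± 0.31, and IDO1, a tryptophan-degrading enzyme, rose by 2.86 ± 0.64 but was at -1.11 with all libraries. In the B and plasma cell list 3 of 23 genes rose, and 13 adjusted over the list alone (adjusted p = 0.0731 with an estimated correlation), among them SPIB at 2.36 ± 0.47. In the regulatory T cell list 2 of 14 rose, and 9 adjusted over the list alone (adjusted p = 0.054 with an estimated correlation), with CTLA4, an inhibitory receptor, at 3.17 ± 0.63. None of 32 proliferation genes passed over all genes tested by edgeR, though 25 did adjusted over the list alone (camera adjusted p = 4.3e-17, but adjusted p = 0.225 with an estimated correlation).

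CLCA1, LGALS15 and 3 genes of the type 2 immunity list also rose with those libraries left out. CLCA1, a secreted protein of mucous cells, rose by 4.28 ± 0.95 (adjusted p = 0.0408). It had 31.2 ± 15.2 CPM in controls (SD, n = 5) and 610 ± 764 CPM in infected lambs (SD, n = 7), and 6 of the 7 lay above every control. LGALS15, the galectin-15 gene, rose by 11.47 ± 2.34 (adjusted p = 0.0332), from 0.0808 ± 0.0781 to 246 ± 450 CPM. Of 19 type 2 immunity genes 3 rose, 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.14e-05, but adjusted p = 0.0705 with an estimated correlation), including FCER2, the low-affinity IgE receptor, at 3.84 ± 0.86 and IL1RL1, the interleukin 33 receptor, at 1.6 ± 0.37. IL13 was at 3.62 ± 0.98 and did not pass (adjusted p = 0.0849). As labelled LGALS15 passed, at 10.51 (adjusted p = 0.0323), and CLCA1 was at 1.53 (adjusted p = 0.883). Of the 19 type 2 genes 1 then rose (adjusted p = 0.131 for the list with an estimated correlation). It was IL17RB, which is also on the tuft cell list and rose with and without those libraries. IL1RL1 is also on the mast cell list, so the type 2 list is not separate from the tuft and mast cell lists. The lower genes included MELTF at -1.36 ± 0.28, B4GALNT3 at -0.8 ± 0.14 and ETV5 at -0.74 ± 0.16. Parietal cell genes had a median of -0.265 with none of 20 passing in edgeR (camera adjusted p = 0.0231, but adjusted p = 0.79 with an estimated correlation). The count of 125 was 3 without control 1, 15 without control 2, 7 without control 3, 231 without control 5, 6 without control 6, 12 without infected 2, 81 without infected 3, 15 without infected 4, 330 without infected 5 and 188 without infected 7, and RGS13, SH2D6 and TRPM5 passed in each of these fits. DESeq2 called 535 genes and limma voom 8. Of the genes named for this comparison RGS13, PSMB8, HOPX, MELTF and B4GALNT3 passed in limma voom, and the other tuft cell genes and the named genes of the mast cell, T cell, B cell, regulatory T cell and type 2 lists did not, nor did TAP1, IDO1, CLCA1, ETV5 or LGALS15 (adjusted p = 0.715 for LGALS15).

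**Figure D2:**
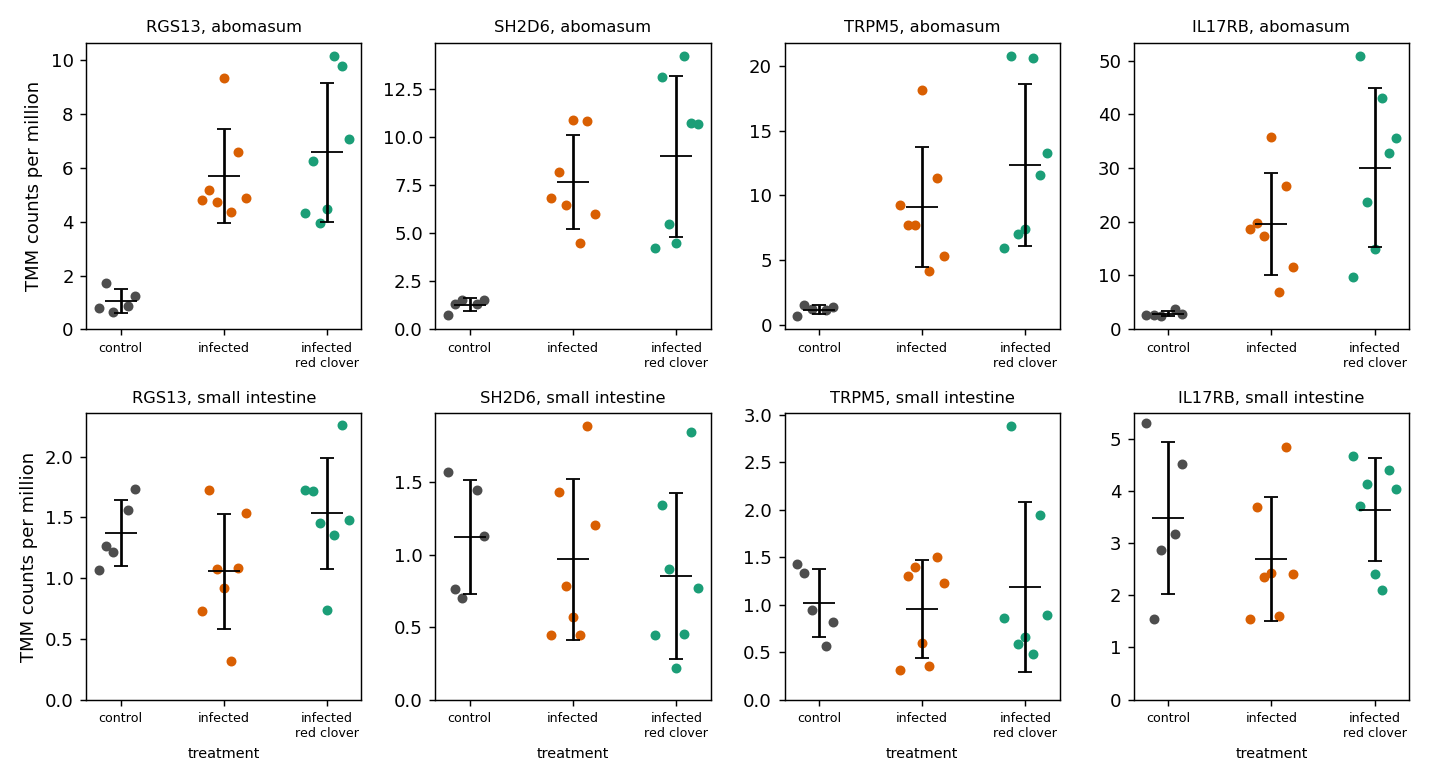
TMM-scaled CPM of RGS13, SH2D6, TRPM5 and IL17RB in each library of both tissues by group, without the libraries labelled control 4, with mean ± SD bars (n = 5 control, 7 infected, 7 infected red clover). In abomasum RGS13 averaged 1.06 CPM in control, 5.7 in infected and 6.57 in infected red clover lambs.

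Red clover against ryegrass among infected lambs gave no gene past the threshold in the abomasum. edgeR called 0 of 15654 genes as labelled, with 406 at an unadjusted p under 0.05, and 0 of 15716 without the libraries labelled control 4, with 768 at an unadjusted p under 0.05. DESeq2 called 0 and 3, and limma voom 0 and 0. The gene with the lowest p was CYP1A1, a xenobiotic-metabolising enzyme induced through the aryl hydrocarbon receptor, at 13.3 ± 7.66 CPM on clover and 2.09 ± 1.29 CPM on ryegrass (SD, n = 7 each; log2 fold change 2.66 ± 0.52, adjusted p = 0.947). Controls had 5.96 ± 6.34 CPM (SD, n = 5). CREB3L3 was at 1.88 ± 0.43, GAPT at -0.49 ± 0.1, RAD54L2 at -0.44 ± 0.1 and DDX6 at -0.36 ± 0.08, all with adjusted p = 0.947. All 32 proliferation genes had higher estimates on clover, with a median of 0.564 (camera adjusted p = 3.17e-21, but adjusted p = 0.871 with an estimated correlation). Interferon response genes had higher estimates in 30 of 33 (camera adjusted p = 1.38e-05, but adjusted p = 0.958 with an estimated correlation), and none of either list passed in edgeR adjusted over the list alone.

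Infected lambs on red clover gave more abomasal calls against controls, though clover against ryegrass among infected lambs gave none by edgeR. Without the libraries labelled control 4, the 10 top genes took 39.8 ± 8.68% of counts on clover and 47.2 ± 6.53% in controls. The effect of that share as a covariate was not examined for this comparison. As labelled, edgeR called 28 genes higher and 4 lower, against 235 called by DESeq2 and 1104 by limma voom, and without the libraries labelled control 4, 803 were higher and 311 lower, which included all 32. Tuft cell genes were again among the higher ones. TRPM5 rose by 3.4 ± 0.42, IL17RB by 3.39 ± 0.43, SH2D6 by 2.8 ± 0.35 and RGS13 by 2.62 ± 0.32 (adjusted p = 8.06e-04 for each), and 14 of 23 list members rose, 15 adjusted over the list alone (adjusted p = 0.0189 with an estimated correlation). Of 15 mast cell genes 9 rose, and 10 adjusted over the list alone (adjusted p = 0.0189 with an estimated correlation). The other lists lost their calls with an estimated correlation. Of 32 proliferation genes 29 rose, and 32 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation), among them the mitotic kinases AURKA at 1.94 ± 0.39 and BUB1 at 1.93 ± 0.37. Of 33 interferon response genes 27 rose, and 33 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation), with PSMB8 at 2.49 ± 0.36 and IRF9 at 1.31 ± 0.25. Of 26 T cell and cytotoxic genes 20 rose, and 22 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation), with CD3E at 1.95 ± 0.36. IL13 rose by 3.32 ± 0.98 (adjusted p = 0.0464), and IL5RA, the interleukin 5 receptor of eosinophils, by 3.5 ± 0.9. As labelled 10 tuft cell, 2 mast cell and 2 interferon response genes rose by edgeR, which passed no proliferation or T cell gene, while limma voom passed genes of both lists, such as CENPF (adjusted p = 0.02) and NKG7 (adjusted p = 0.0202). With an estimated correlation the lists of tuft cells (adjusted p = 4.45e-04), mast cells (adjusted p = 0.00442), eosinophils and basophils (adjusted p = 0.0288) and antimicrobial and defence genes (adjusted p = 0.0495) then passed.

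The named genes of this comparison without the libraries labelled control 4 also included epithelial ones that rose and others that fell. TFF3, a trefoil peptide of intestinal goblet cells, rose by 6.89 ± 1.32, from 1.09 ± 1.28 CPM in controls (SD, n = 5) to 128 ± 168 CPM (SD, n = 7), and CLCA1 rose by 4.84 ± 0.97. MUC5AC, the gel-forming mucin of gastric surface cells, was lower by a log2 fold change of -1.61 ± 0.33, at 4034 ± 1681 CPM in controls and 1324 ± 686 CPM on clover, and GKN1 and GKN2, gastrokines of the same cells, were at -1.24 ± 0.25 and -1.17 ± 0.3. These are the 3 of 15 gastric surface and neck genes that fell, also adjusted over the list alone (camera adjusted p = 0.0247, but adjusted p = 0.539 with an estimated correlation). DUOX2, an epithelial oxidase, rose by 1.6 ± 0.46 with its maturation factor DUOXA2 at 1.76 ± 0.38, the 2 of 13 antimicrobial and defence genes that passed, against 8 adjusted over the list alone (camera adjusted p = 6.71e-04, but adjusted p = 0.105 with an estimated correlation). CCKAR, a cholecystokinin receptor, was lower at -1.92 ± 0.32, and the matrix genes DCN and PDGFRB at -0.7 ± 0.18 and -0.48 ± 0.13. As labelled none of the genes named since TFF3 passed, with TFF3 at 1.13 (adjusted p = 0.794), and the median of the gastric surface and neck list was 0.15 against -0.123 without those libraries. The count of 1114 was 339 without control 1, 594 without control 2, 634 without control 3, 559 without control 6, 690 without clover 5, 716 without clover 6 and 725 without clover 7, and 264 genes passed with any one library left out. DESeq2 called 1796 genes.

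**Figure D3:**
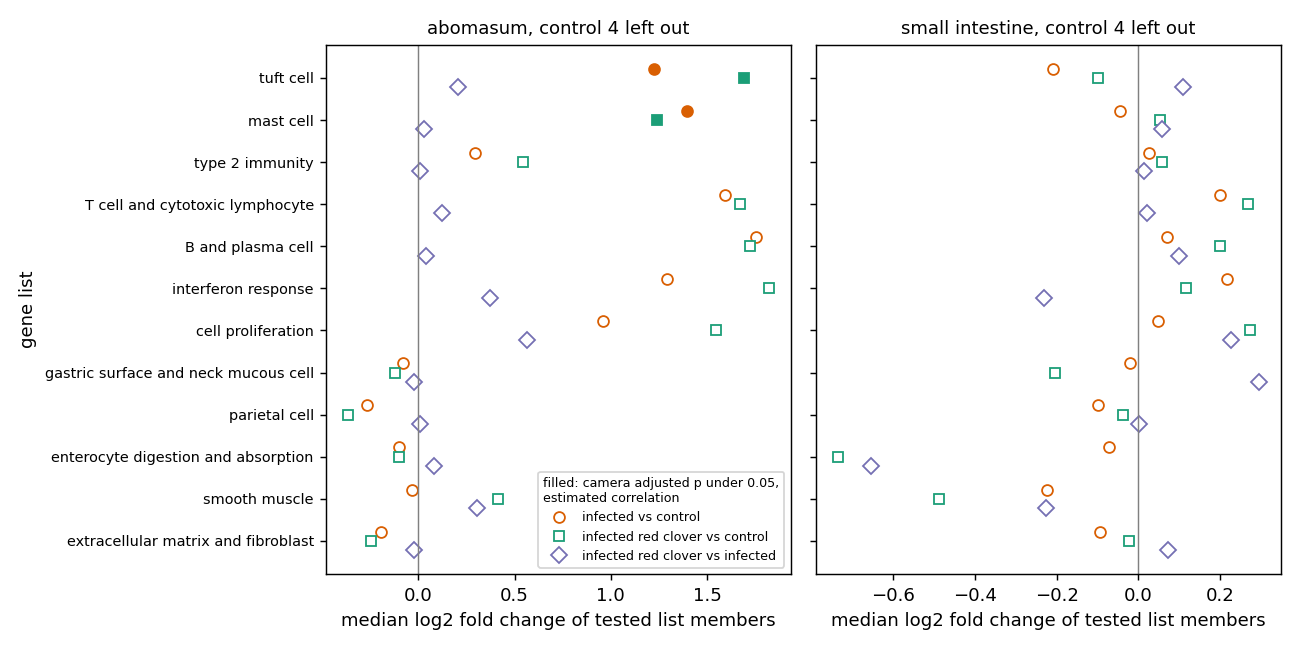
Median log2 fold change of 12 gene lists in each comparison, without the libraries labelled control 4, filled where camera with an estimated correlation gave an adjusted p under 0.05. The filled points are the tuft and mast cell lists in abomasum, with tuft cell medians of 1.22 in infected and 1.69 in infected red clover lambs against control.

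Both infected groups were compared with the same controls, so their calls were set beside simulations. In abomasum 13 genes were called in the same direction in both comparisons as labelled and 123 without the libraries labelled control 4. Unchanged groups simulated against those controls shared 0.87 calls on average as labelled (0 to 87) and 0.08 without them (0 to 6), and independent lists would share 6.03 higher and 0.139 lower genes in the latter case. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.368 as labelled against 0.241 in simulation, within the simulated range of 0.00264 to 0.893, and 0.0482 with split controls. Without those libraries it was 0.321 against 0.0805, above the simulated range of 7.28e-04 to 0.277, a difference of 0.241. It was 0.287 with split controls, and r was 0.902 against 0.589 in simulation. The simulations resampled the control libraries, so as labelled their ranges carry the libraries labelled control 4. They drew each gene independently, so genes that vary together could make the ranges wider than given. With the controls split between the comparisons the median shared count was 3.5 as labelled (0 to 6) and 0 without those libraries, where each comparison kept 2 or 3 controls. In small intestine the shared count was 0 by edgeR both ways, where unchanged groups shared 56.9 as labelled (0 to 2347) and 0 without those libraries. The covariance there was 0.314 as labelled against 0.168 in simulation (0.00172 to 0.601) and 0.0774 without those libraries against 0.0503 (3.88e-04 to 0.16), so both lay within the range of unchanged groups.

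In the small intestine, infection on ryegrass gave no call. edgeR called 0 of 15929 genes as labelled, with 2168 at an unadjusted p under 0.05, and 0 of 16012 without the libraries labelled control 4, with 1264 at an unadjusted p under 0.05. DESeq2 called 11 and 4, and limma voom 2 and 0. The lowest p values, all at adjusted p = 0.516, belonged to genes that included CD4, the co-receptor of helper T cells, at 58.5 ± 7.24 CPM in infected lambs (SD, n = 7) and 42 ± 4.26 CPM in controls (SD, n = 5), PDCD1, an inhibitory receptor of T cells, at 0.96 ± 0.22, METTL23 at 0.69 ± 0.16, DCAF16 at -0.39 ± 0.09 and WDR19 at -0.59 ± 0.13. IFNG was at 1.13 ± 0.36 (adjusted p = 0.618) and IL13 at 0.14 ± 0.57 (adjusted p = 0.962). Of 27 T cell and cytotoxic genes 22 had higher estimates, with 1 passing adjusted over the list alone (camera adjusted p = 4.83e-05, but adjusted p = 0.869 with an estimated correlation). Tuft cell genes had a median of -0.208, with higher estimates in 4 of 23 and none passing adjusted over the list alone in edgeR (camera adjusted p = 0.0348, but adjusted p = 0.869 with an estimated correlation). As labelled, 1 gene passed without control 6 and 1 without clover 7.

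Red clover against ryegrass among infected lambs gave no call by edgeR in the small intestine either. As labelled 0 of 15929 genes passed, with 507 at an unadjusted p under 0.05, and 0 of 16012 without the libraries labelled control 4, with 1056 at an unadjusted p under 0.05. DESeq2 called 1 and 11, and limma voom 0 and 0. SELENOW, a small selenoprotein, was at 32.7 ± 2.67 CPM on clover and 52.2 ± 12.1 CPM on ryegrass (SD, n = 7 each), with all 7 clover libraries below every ryegrass library and a log2 fold change of -0.67 ± 0.11 (adjusted p = 0.172). GPX1, a selenium-dependent glutathione peroxidase, was at -0.72 ± 0.15, NR0B2, a repressor in bile acid signalling, at -1.52 ± 0.32, GAL3ST1, a sulfotransferase, at -3.41 ± 0.73 and BCAT1, a branched-chain aminotransferase, at 0.98 ± 0.2, each with adjusted p = 0.531. Of 29 enterocyte genes 3 had higher estimates, with a median of -0.653 and 1 passing as lower adjusted over the list alone (camera adjusted p = 6.93e-18, but adjusted p = 0.282 with an estimated correlation). All 32 proliferation genes had higher estimates, with a median of 0.227 (camera adjusted p = 1.66e-06, but adjusted p = 0.704 with an estimated correlation). Leaving out infected 4 as well gave 1 call.

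Infected lambs on red clover differed from controls in few intestinal genes. As labelled, 10 were higher and 3 lower, and without the libraries labelled control 4, 15 were higher and 2 lower, with 10 genes in common. Without them, the named genes that rose included HSPA8, a constitutive chaperone, at 0.95 ± 0.18, HSP90AA1 at 0.81 ± 0.15, and the co-chaperones CHORDC1 at 0.77 ± 0.14, STIP1 at 0.73 ± 0.13 and DNAJA1 at 0.73 ± 0.13. PSAT1, an enzyme of serine synthesis, rose from 15.5 ± 6.41 CPM (SD, n = 5) to 87.5 ± 58.1 CPM (SD, n = 7; log2 fold change 2.51 ± 0.45, adjusted p = 0.0403), BCAT1 rose by 1.18 ± 0.23 and CD4 by 0.62 ± 0.1. SELENOW was lower at -0.67 ± 0.12 (adjusted p = 0.0401) and TMEM164 at -0.37 ± 0.07. GAL3ST1 at -4.53 ± 0.82 and JMJD6 at 0.55 ± 0.1 passed as labelled and missed the threshold without those libraries (adjusted p = 0.0527 for each). As labelled HSP90AA1 (adjusted p = 0.0546), PSAT1 (adjusted p = 0.269), BCAT1 (adjusted p = 0.0693), CD4 (adjusted p = 0.242) and SELENOW (adjusted p = 0.07) did not pass. Of 29 enterocyte genes 1 had a higher estimate, with a median of -0.736 and none passing adjusted over the list alone in edgeR (camera adjusted p = 1.15e-11, but adjusted p = 0.641 with an estimated correlation). The count of 17 was 1 without control 2, 3 or 5, 60 without control 1, 10 without control 6, 3 without infected 1 or 2, 4 without infected 6, 34 without infected 7 or clover 1, 114 without clover 3, 2 without clover 4, 3 without clover 5 or 6 and 5 without clover 7. LOC101119835, outside the rule for named genes since it has a locus identifier alone, rose by 0.98 ± 0.13 (edgeR adjusted p = 0.00628). It was the only gene of the 17 that passed with each library left out in turn. Every named gene thus lost its call without some library. DESeq2 called 283 genes, limma voom 30, and a fit of only the groups compared 5.

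The effect of infection on ryegrass was then compared between the tissues, as small intestine minus abomasum. As labelled 113 differences were positive and 82 negative among 16460 genes, and the largest were those of tissue markers, such as FABP2 at 14.48 and ATP4A at -13.99. Without the libraries labelled control 4, no difference was positive and 38 were negative among 16535 genes, with 10 genes in common. RGS13 differed by -2.81 ± 0.44 (adjusted p = 0.00163), with log2 fold changes of 2.42 in abomasum and -0.37 in small intestine. CHAT differed by -3.08 ± 0.48, IL17RB by -3.17 ± 0.52, ALOX5 by -2.58 ± 0.42, TRPM5 by -3.08 ± 0.63 and SH2D6 by -2.82 ± 0.57. TFF3 differed by -4.96 ± 1.07, CLCA1 by -4.37 ± 0.86 and PSMB8 by -1.77 ± 0.36. Both tissues came from the same lambs, although the labels do not say that a number marks the same lamb in both. With the lamb, taken as treatment and number, as a block the 195 became 5 as labelled and the 38 became 13, each a part of the count without the block. RGS13, CHAT, IL17RB, ALOX5, TRPM5 and SH2D6 passed with the block too, and TFF3 (adjusted p = 0.0993), CLCA1 (adjusted p = 0.0889) and PSMB8 (adjusted p = 0.0993) did not. The count of 38 was 8 without abomasum control 1, 18 without control 3, 206 without control 5, 6 without control 6, 19 without infected 2, 10 without infected 4, 163 without infected 5, 151 without infected 6, 110 without infected 7, and 78, 64, 73 and 74 without clover 1, 2, 4 and 5 of that tissue, and 13 and 18 without small intestine control 5 and 6. DESeq2 called 233 differences and limma voom 2. For red clover against ryegrass edgeR found 0 tissue differences both ways, with 305 genes at an unadjusted p under 0.05 as labelled and 653 without the libraries labelled control 4, DESeq2 found 31 and 3, and limma voom 0 and 0.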

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

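The tests on the tissue profile of the libraries labelled control 4, on a lower share of gastric gland cells and on stress of the whole lamb were chosen after the result was seen, and so were leaving out those libraries and the splits of whole lambs. The other tests were written down before their results were seen.

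The libraries labelled control 4 stood apart within their groups. Each gap to the nearest other library is given as a share of the group's range. In abomasum controls this gap was 0.688 for total counts, at 44438500 in that library, 0.675 for the share of counts in the 10 top genes, at 11.1%, and 0.974 for ATP4A, at -1.96 on the log2 scale. In small intestine controls it was 0.971 for the share in the 10 top genes, at 62.2%, and 0.902 for FABP2, at 0.413 on the log2 scale. An exchange of the control 4 libraries between the tissues predicts that both carry the other tissue's markers throughout, and of 47 marker genes, 47 and 46 lay at the other tissue's level, 97.9% in the lower case. A mixed sample would keep part of its own tissue's transcripts, and ATP4A in the library labelled abomasum control 4 was 0.00281% of the median of the other abomasum libraries, which argues against a mixture. Where an exchange took place, and whether it involved this lamb's own samples, stays open, and no biological explanation was tested.

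Single genes also had a library far from its group, with the libraries labelled control 4 left out for genes other than ATP4A and FABP2. Over 196 tests of single genes in groups without those libraries 10 exceeded Dixon's limit, and chance gives about 1 in 20 groups. Over all 210 tests, with total counts, shares and the groups that hold those libraries, 15 did. In abomasum controls the gap was 0.754 for SH2D6, 0.746 for CD8A and 0.744 for DENND11, each in control 1, and 0.711 for CD3D in control 5. In infected abomasum it was 0.632 for DENND11 in infected 1. On red clover it was 0.623 for ATP4A in clover 2, 0.593 for DUOX2 in clover 4 and 0.629 for DDX6 in clover 6 in abomasum, and 0.587 for FABP2 in clover 3 in small intestine. In infected small intestine it was 0.586 for IL13 in infected 7.

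The effect of infection differed between the tissues for 15 named genes by the test of the difference itself, as small intestine minus abomasum on the log2 scale without the libraries labelled control 4. The tuft cell genes were RGS13 at -2.81, SH2D6 at -2.82, TRPM5 at -3.08, CHAT at -3.08, IL17RB at -3.17 and ALOX5 at -2.58. The others were LGALS15 at -12.69, TFF3 at -4.96, CLCA1 at -4.37, COL6A5 at -4.06, SPIB at -2.11, ADORA3 at -1.83, PSMB8 at -1.77, HMOX1 at -1.45 and PIM2 at -1.29. With the lamb as a block the tuft cell genes, COL6A5 and HMOX1 passed, and LGALS15, TFF3, CLCA1, SPIB, ADORA3, PSMB8 and PIM2 did not. The count of 38 differences without the block had 2 of 100 splits as large, the real one included, with the tissues split separately and a highest other of 150. Of 40 splits of whole lambs 1 was as large, with a highest other of 10, which is the lowest share that test can reach. Chance is therefore unlikely for that count, but it was not excluded. With the lamb as a block the count was 13, and 2 of the 40 splits of lambs were as large, with a highest other of 62, so chance cannot be excluded for it. Splits that call several times the real count point to a structure of the samples. As labelled, 14 of 100 splits were as large as the real 195, with a highest other of 612, and chance cannot be excluded.

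Tuft cell genes in the abomasum of infected lambs were weighed against technical explanations. The 10 top genes took 47.2 ± 6.53% of counts in controls, 41.4 ± 10.8% in infected and 39.8 ± 8.68% in infected red clover lambs. With that share as a covariate the median log2 fold change of the list was 1.04 against 1.22 without it, and 9 members passed against 10, while all calls went from 125 to 30, which argues against a few genes taking most of the counts as the whole cause. A lower share of gastric gland cells would raise markers of all other types alike. The tuft cell score less the mean score of stroma, muscle, nerve and enteroendocrine cells differed by 1.22 ± 0.21 (two-sided exact permutation p = 0.00126, adjusted p = 0.00504 over 8 score tests), so these types did not rise alike. Immune cells were not among them. Without the genes that the lists share, the median was 1.08 for mast cell genes and 1.13 for tuft cell genes, so the test does not decide. A rise in tuft cells or in their transcripts with infection may account for the pattern, as a hypothesis, since it was found and tested on the same lambs. A lower share of gland cells, slaughter day and pen stay open.

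Heat shock genes in the small intestine of infected red clover lambs were weighed in the same way. The 7 genes noticed were higher than in controls by 0.8 ± 0.16 on the log2 scale (two-sided exact permutation p = 0.00253, adjusted p = 0.00675), on genes picked because they showed it. Their estimates were also above 0 in infected lambs on ryegrass against control, from 0.39 to 0.67, and in clover against ryegrass, from 0.16 to 0.59, and none of these passed in edgeR. Of 16 other heat shock genes, 14 were tested, and their mean was higher by 0.44 ± 0.12 (exact permutation p = 0.00884, adjusted p = 0.0141), as a heat shock response predicts. The 7 genes were also higher in abomasum, by 0.42 ± 0.11 (exact permutation p = 0.00379, adjusted p = 0.00758), so stress of the whole lamb at slaughter may account for it as well as diet or infection. Slaughter day is not labelled per library, which keeps these explanations open.

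Other splits of the same libraries bear on the counts of genes, with 100 splits in each case and the real one included. In abomasum without the libraries labelled control 4, infected against control gave 125 against a highest other of 1, with 1 split as large. Infected red clover against control gave 1114 against 180, with 1 split as large. No other split was as large in either, so chance is an unlikely source of both counts. As labelled these were 13 against 1468 and 32 against 1975, with 2 splits as large in each. Few splits were as large, but splits that call that many genes point to a structure of the samples, so chance was not excluded. Infected red clover against control in small intestine gave 13 against 2 as labelled, with 1 split as large. Each of these splits holds the library labelled small intestine control 4 in a group compared. Chance is therefore unlikely for that count, but it was not excluded. Without the libraries labelled control 4 the same comparison gave 17 against 256, with 2 as large. The split with 256 again points to a structure, so chance was not excluded. For the comparisons with 0 calls the splits decide nothing, since any split gives at least 0, and 100 of 100 were as large. Their highest others in abomasum clover against ryegrass were 0 as labelled and 35 without those libraries, in small intestine infected against control 0 and 2, in small intestine clover against ryegrass 0 and 1, and in the tissue difference of diet 1 and 183.

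For the number of gene lists past the camera threshold, chance could not be excluded in any comparison. As labelled, in abomasum, infected against control gave 17 lists against a highest other of 20, with 12 splits as large, clover against ryegrass gave 4 against 17, with 96, and infected red clover against control gave 18 against 22, with 12. In small intestine the same comparisons gave 9 against 19, with 89, 7 against 14, with 62, and 10 against 20, with 83. Without the libraries labelled control 4, in abomasum they gave 13 against 17, with 35, 5 against 18, with 95, and 14 against 19, with 29. In small intestine they gave 8 against 15, with 60, 11 against 16, with 39, and 11 against 18, with 32.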

How the results depend on the processing

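Leaving out the libraries labelled control 4, with each alternative run on that set, was chosen after the result was seen, and the other alternatives were planned. The cause of each difference below was not tested unless stated.

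As labelled, infected against control in abomasum gave 13 genes and 7 with the replicate block, 7 with limma voom, 69 with DESeq2 and 125 without those libraries. Infected red clover against control gave 32 and 17 with the replicate block, 16 with only the groups compared, 1104 with limma voom, 235 with DESeq2 and 1114 without those libraries. In small intestine infected against control gave 0 and 2 with limma voom and 11 with DESeq2, clover against ryegrass gave 0 and 1 with DESeq2, and infected red clover against control gave 13 and 7 with no filter, 0 with the replicate block, 0 with only the groups compared, 34 with limma voom, 292 with DESeq2 and 5 with the fold threshold. The tissue difference of infection gave 195 and 2 with limma voom, 402 with DESeq2, 5 with the lamb as a replicate block and 38 without those libraries, and that of diet 0 and 31 with DESeq2. Without the libraries labelled control 4, infected against control in abomasum gave 125 and 4 with the replicate block, 32 with only the groups compared, 8 with limma voom and 535 with DESeq2. Clover against ryegrass gave 0 and 3 with DESeq2. Infected red clover against control gave 1114 and 735 with the replicate block, 1796 with DESeq2 and 623 with the fold threshold. In small intestine the 3 comparisons gave 0 and 4 with DESeq2, 0 and 11 with DESeq2, and 17 and 0 with the replicate block, 5 with only the groups compared, 30 with limma voom, 283 with DESeq2 and 5 with the fold threshold. The tissue difference of infection gave 38 and 2 with limma voom, 233 with DESeq2 and 13 with the lamb as a replicate block, and that of diet 0 and 3 with DESeq2.

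With each library left out in turn, as labelled, the counts ranged from 7 to 125, 0 to 0 and 14 to 1114 in abomasum for infected against control, clover against ryegrass and infected red clover against control, from 0 to 1, 0 to 0 and 1 to 102 in small intestine, and from 50 to 288 and 0 to 0 for the tissue differences of infection and diet. Without the libraries labelled control 4 they ranged from 3 to 330, 0 to 0 and 339 to 1644 in abomasum, 0 to 0, 0 to 1 and 1 to 114 in small intestine, and 6 to 206 and 0 to 1 for the tissue differences. The lowest and highest were without control 1 and control 4 for 7 and 125, control 2 and control 4 for 14 and 1114, control 2 and control 1 for 1 and 102, abomasum control 4 and abomasum control 1 for 50 and 288, control 1 and infected 5 for 3 and 330, control 1 and clover 1 for 339 and 1644, control 2 and clover 3 for 1 and 114, and abomasum control 6 and abomasum control 5 for 6 and 206.

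Other libraries that moved a count as labelled by over 1.5 times were these. The 13 genes of infected against control in abomasum became 7 without control 3 or infected 2, 4 or 6, and 8 without control 2 or 6 or infected 3. The 32 of infected red clover against control became 19 without control 1, 17 without control 6 or clover 2, 21 without infected 2 or 6, 65 without clover 1, 16 without clover 5 or 7 and 15 without clover 6. The 13 in small intestine became 6 without control 3 or infected 3, 1 without control 5 or clover 6, 4 without infected 2, 7 without infected 5 or clover 7, 8 without infected 6 or clover 1, 54 without clover 3, 3 without clover 4 and 2 without clover 5. The 195 tissue differences became 119 without abomasum infected 4 and 95 without small intestine control 4.

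Gene lists past camera as labelled went from 17 to 3 with an estimated correlation and 3 with fry, from 4 to 0 and 0, and from 18 to 4 and 6 in abomasum, and from 9 to 0 and 0, 7 to 0 and 0, and 10 to 0 and 1 in small intestine, where clover against ryegrass gave 11 without those libraries. Without them, lists went from 13 to 2 with an estimated correlation, from 5 to 0 and 0 with fry, and from 14 to 2 in abomasum, and from 8 to 0 and 0, 11 to 0 and 0, and 11 to 0 and 1 in small intestine. The shared count of 13 was 3.5 with split controls, and 123 was 0, where fewer controls per comparison are part of the construction. IDO1 and CD3D turned to -1.11 and -0.03 in abomasum with all libraries. IL13 in small intestine, at 0.14, was at -0.05 with limma voom, -0.09 without control 2, -0.12 without infected 2 and -0.13 without infected 6, and at most 0.36, without infected 7.

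Over named genes and settings, 2085 of 2703 results kept their direction and side of the threshold, 587 lost their call, 25 gained one and 6 changed sign. By setting, 41 of 104 were kept with all libraries as labelled, 53 of 104 with the replicate block, 62 of 104 with limma voom, 71 of 103 with only the groups compared, 93 of 104 with DESeq2, 95 of 104 with no filter, 101 of 104 with RLE scaling and 1569 of 1976 with a library left out. Lambs in different groups share only a number, and across tissues the correlation of same-numbered deviations averaged 0.134 in control, 0.202 in infected and 0.124 in clover lambs, against -0.033, -0.033 and -0.021 for other numbers, and was as low as 0.055, with 4 of 5 control, 6 of 7 infected and 3 of 7 clover libraries matching their own number best. The planned sex covariate was not run, since 0 of its genes were in the table. At 27538694 to 44968690 counts per library, simulated 1.5-fold changes were recovered in 35.8% of genes in abomasum and 51.5% in small intestine for infected against control without those libraries.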

Other observations

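The tuft cell regulators, the intestinal genes and the gene lists of the hypotheses were chosen after the result was seen. The tests of the hypotheses were written down before their results were seen.

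Among other genes linked to tuft cells, which were not tested as a list, these values are for the abomasum without the libraries labelled control 4. HMX2 and HMX3, a pair of homeobox genes, rose in infected against control lambs by 3.49 ± 0.63 (edgeR adjusted p = 0.0246) and 2.01 ± 0.39 (adjusted p = 0.0282), and in infected red clover lambs by 4.22 ± 0.63 and 2.37 ± 0.39. C15H11orf53 and COLCA2 carry the names of genes for coactivators of POU2F3. C15H11orf53 rose by 2.31 ± 0.47 (adjusted p = 0.0313) and 2.51 ± 0.47, and COLCA2 was at 1.07 ± 0.32 (adjusted p = 0.129) and rose by 1.52 ± 0.33 (adjusted p = 0.0149). As labelled HMX2 was at 2.93 in infected lambs (adjusted p = 0.0625) and COLCA2 at 1.3 (adjusted p = 0.247) and at 1.74 on clover (adjusted p = 0.07), and these did not pass, while the others did. HMX2 stayed low, at 0.573 ± 0.245 CPM in infected lambs (SD, n = 7). In small intestine HMX3 was at -1.05 ± 0.49 in infected against control (adjusted p = 0.626), and C15H11orf53 at 0.03 ± 0.76.

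CDX1, a transcription factor of intestinal epithelium, and MGAM, a brush border enzyme, were at low levels in the abomasum of both infected groups without the libraries labelled control 4. CDX1 was at 0.109 ± 0.107 CPM in controls (SD, n = 5), 0.621 ± 0.35 in infected and 0.665 ± 0.456 in infected red clover lambs (SD, n = 7 each), and MGAM at 0.088 ± 0.086, 0.332 ± 0.193 and 0.51 ± 0.345 CPM. Against control, CDX1 was at 2.47 ± 0.74 in infected lambs (edgeR adjusted p = 0.126) and rose by 2.57 ± 0.74 on clover (adjusted p = 0.0407), and MGAM was at 1.92 ± 0.72 (adjusted p = 0.229) and rose by 2.55 ± 0.71 (adjusted p = 0.0356). Clover against ryegrass was at 0.1 ± 0.55 for CDX1 (adjusted p = 0.994) and 0.63 ± 0.54 for MGAM (adjusted p = 0.958). Of 16 enterocyte genes 2 rose on clover against control, and the list did not pass (camera adjusted p = 0.781). In that comparison with all libraries CDX1 was at -2.04 and MGAM at -6.56, and neither passed.

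A first hypothesis was that the lower estimates of SELENOW and GPX1 in small intestine on red clover were part of lower selenoprotein transcripts as a class. Against ryegrass among infected lambs neither gene passed (edgeR adjusted p = 0.172 and adjusted p = 0.531), and against control SELENOW alone of them did, without the libraries labelled control 4. The mean of 19 other selenoprotein genes differed by -0.03 ± 0.06 between clover and ryegrass among infected lambs (two-sided exact permutation p = 0.605, adjusted p = 0.691), which argues against a change of the whole class.

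A second hypothesis was that the higher estimates of PSAT1 and BCAT1 in small intestine on red clover were part of an amino acid response. Both passed against control without the libraries labelled control 4, but in clover against ryegrass among infected lambs, where the test was made, PSAT1 was at 1.64 ± 0.39 (edgeR adjusted p = 0.729) and BCAT1 at 0.98 ± 0.2 (adjusted p = 0.531) and neither passed. The mean of 23 other genes of that response was higher by 0.28 ± 0.11 on clover than on ryegrass (two-sided exact permutation p = 0.0233, adjusted p = 0.0311). This goes with the hypothesis as a difference of the mean, with no single gene called, and was found and tested on the same lambs. In infected lambs on ryegrass against control most of these genes were also above 0, such as GARS1 at 0.44 ± 0.18 and SLC7A5 at 0.43 ± 0.21. Others were below, such as STC2 at -0.64 ± 0.29, and none passed in edgeR. The tests did not separate diet from pen or slaughter day, which stay open.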
